A study of Homo sapiens with 12 samples.

How the data were processed

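RNA was measured by sequencing in OCI-AML2 cells, a human line derived from acute myeloid leukaemia. Single-cell clones carried a doxycycline-inducible construct for the transcription factor MEF2C, either wild type (WT) or with the S222A change, which replaces a serine by alanine. Per the labels' protocols, cells in 3 ml were kept with 600 ng doxycycline or with vehicle for 48 h before RNA extraction, and no volume is given for the doxycycline amount. Libraries were made with a TruSeq RNA kit, per the labels' protocols. The 12 libraries form 4 groups of 3: WT uninduced, WT induced, S222A uninduced and S222A induced, as the sample titles give them. No label says that the 3 replicates of a group are separate cultures, so p-values measure the spread between these samples, which may be technical. The number of clones per construct is not stated, and cells without a MEF2C construct that received doxycycline are not among the samples analysed here.

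The authors deposited 1 table of raw counts per gene symbol, with 12 columns of whole-number counts and no normalization. Its header line has 1 tab fewer than the data lines, with a space between the last names, so columns were matched to samples by position and by their names, which are the sample descriptions in the labels. The S222A columns are named MEF2Cun and MEF2Cind with no S222A in the name, and every group rests on this match with the sample titles. Per the submitters' processing notes, the genome build was hg19 and the tools were STAR 2.4, HTSeq 0.6.1 and DESeq2, with no role, order or DESeq2 version given. The annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of MEF2C and of its antisense neighbour MEF2C-AS1 cannot be told apart, and counts per symbol do not separate transgene from endogenous MEF2C reads. Genes with near-identical copies, such as the replication-dependent histones, share reads and are uncertain for that reason. No coordinates are reported.

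The table held 55765 genes, of which 24318 had no count in any library. Totals were 1941128, 5412391 and 2348855 counts for WT uninduced replicates 1 to 3, and 7294463, 875710 and 3718797 for WT induced. They were 8660836, 2365154 and 930960 for S222A uninduced, and 2848123, 4489036 and 13134791 for S222A induced. The floor of 3 counts corresponded to between 0.228 and 3.43 counts per 1e6 counts (CPM), covering counting error only. Within each group every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 2.79 and 39.64 over 12 pairs, so no library was treated as a duplicate.

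Genes were kept by edgeR's filterByExpr at its default minimum count of 10, which left 11474 genes holding 99.47% of the counts. With TMM factors and all 12 libraries in 1 model with a mean per group (8 residual degrees of freedom), genes were tested with edgeR 4.0.16 by robust quasi-likelihood F tests in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 24.8%. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of F, and levels are CPM with TMM factors, as mean ± SD with n = 3. Called genes are those with an adjusted p under 0.05, and every adjusted p of a gene is from this test unless another is named.

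There were 5 comparisons: induced against uninduced in the WT line, the same in the S222A line, the difference of these effects (S222A minus WT), the induced lines, and the uninduced lines. Before the data were examined, 40 gene lists were fixed on MEF2 biology, leukaemia stemness, drug response, blood cell types, proliferation, stress, metabolism, inflammation, adhesion and library preparation. Lists with at least 5 tested members, 33 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 33 lists. The list results planned and described are those of the other 4 comparisons; between the induced lines 17 lists were called, 13 with an estimated correlation, and these are not described because no alternatives were planned for them. Each list was tested again with an estimated correlation and with fry. Some lists share genes, BTG2 and LDHA among them. The other 7 lists had 2 or 3 tested members and were not tested as lists. The MEF2 family is described by gene, the others mainly by their called genes on S222A induction.

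Genes are named by a rule fixed at the same time. It takes MEF2C everywhere, up to 10 higher and 10 lower genes with the largest change among those called (5 and 5 between the induced lines), up to 4 members per list with the smallest adjusted p, and all MEF2 family and class IIa histone deacetylase list members on induction. The largest changes also needed a mean of at least 1 log2 CPM and no overlap between the groups compared. Clone-style symbols and genes of the Y chromosome were passed over. A few genes that the rule names are not reported here.

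The model was tested on simulated data with 200 genes changed, at the real means, dispersions and depths. It recovered 22.4% of 2-fold and 83.8% of 4-fold changes for WT induction, 30.6% and 80.8% for S222A induction, 31% and 83.7% between the induced lines, and 23.5% and 79.8% between the uninduced lines. For the difference of effects it recovered 1% of 2-fold and 61% of 4-fold changes. False calls numbered between 1 and 11 among 11004 to 11041 unchanged genes per comparison. Changed genes were drawn only above a minimum mean CPM. Simulated genes varied independently, without the shared spread between the deepest and the other libraries. These rates may therefore not hold for the real libraries, in either direction. Another split of the real WT libraries called up to 109 genes, but it put both deepest WT libraries on the same side, unlike the real groups.

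Alternatives were DESeq2 1.42.0, RLE and upper quartile factors, no low-count filter, a minimum of 1 CPM in 3 libraries, limma-voom, a term for the replicate number, only the groups compared, MEF2C left out, thinning to the lowest total, a minimum fold of 2, and each library left out in turn. A term for the deepest library of each group, and a fit without those libraries, were added after seeing the data. The replicate numbers were not used to pair samples. The random seed was 20240, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.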

Results

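Gene expression was measured in 12 RNA sequencing libraries of clones of OCI-AML2, an acute myeloid leukaemia line. The clones carried a doxycycline-inducible construct for either wild-type (WT) MEF2C or its S222A mutant. MEF2C is a transcription factor of muscle, neurons and blood, and the series title links its phosphorylation to chemotherapy resistance. Each of the 4 groups, uninduced and induced cells of each line, had 3 libraries. Library totals ranged from 875710 to 13134791 counts, a 15-fold range. In a principal component analysis of log2 CPM over 11474 genes, the deepest library of each group (5412391 to 13134791 counts) lay at 33.5 to 44.4 on component 1, which held 33.1% of the variance. The other 8 libraries (875710 to 4489036 counts) lay between -51.3 and -2.2. Mitochondrially encoded RNA made up 5.03 to 7% of counts in those 4 deepest libraries and 6.86 to 9.27% in the other 8. Component 2, with 22% of the variance, placed the S222A induced libraries at 32.6 to 47.2 and all other libraries at -29.9 to 9.4. On component 3, with 16.3% of the variance, S222A uninduced replicate 3 (930960 counts) stood apart at -62.5, with all other libraries at -13.3 to 31.2. Among genes chosen after seeing the data, MYC stood at 53.66 CPM in it against 230.64 and 210.54 CPM in the other S222A uninduced libraries, and RASD1 at 2.19 against 28.35 and 25.86 CPM.

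**Figure D1:**
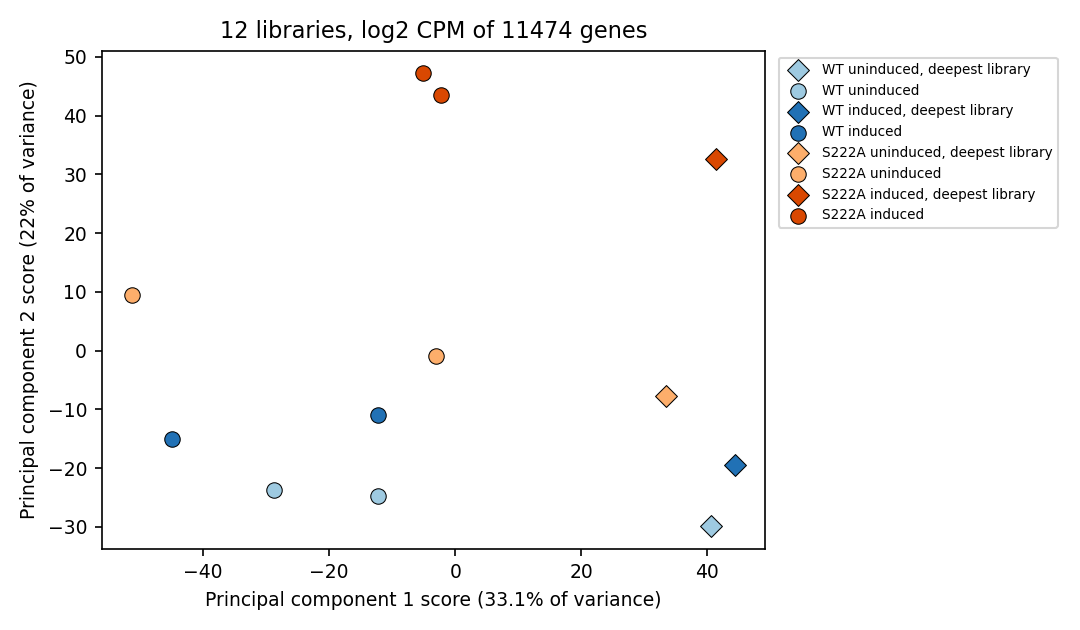
Scores of the 12 libraries on principal components 1 (x axis) and 2 (y axis) of log2 CPM, unitless, with the percent of variance on each axis, coloured by group, with diamonds for the deepest library of each group. The diamonds lie at 33.5 to 44.4 on component 1, and the S222A induced libraries at 32.6 to 47.2 on component 2.

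In the WT line MEF2C stood at 746.9, 645.3 and 816.7 CPM in the uninduced and at 674.4, 844.1 and 812.4 CPM in the induced libraries. The fold was 1.05 (95% interval 0.81 to 1.37; log2 0.08 ± 0.16 SE, edgeR quasi-likelihood adjusted p = 1). In the S222A line MEF2C stood at 605.3, 700.6 and 801.6 CPM uninduced and at 919.5, 956.1 and 786.3 CPM induced. The fold was 1.26 (95% interval 0.97 to 1.64; log2 0.34 ± 0.16 SE, adjusted p = 0.28). A term for the deepest libraries, chosen after seeing the data, gave MEF2C the same log2 of 0.34 in the S222A line with an adjusted p = 0.0282, so MEF2C was called in that fit alone. Within the deepest libraries the log2 fold change of MEF2C was 0.06 in the WT and 0.38 in the S222A line, and within the other 8 libraries 0.08 and 0.32. MEF2C was abundant before induction, so these intervals bound the change of total MEF2C RNA, transgene and endogenous together. Without the term for the deepest libraries no rise of MEF2C RNA was called on either induction, and the groups are named induced by their doxycycline treatment, not by their MEF2C RNA. No difference in MEF2C was called between the lines, with a log2 difference of 0.19 ± 0.16 SE between the induced (adjusted p = 0.56) and -0.07 ± 0.16 SE between the uninduced cells (adjusted p = 1). The other MEF2 family members tested, MEF2A and MEF2D, were not called on either induction: MEF2A had log2 fold changes of 0.34 in the WT and 0.41 in the S222A line, and MEF2D 0.01 and -0.13.

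**Figure D2:**
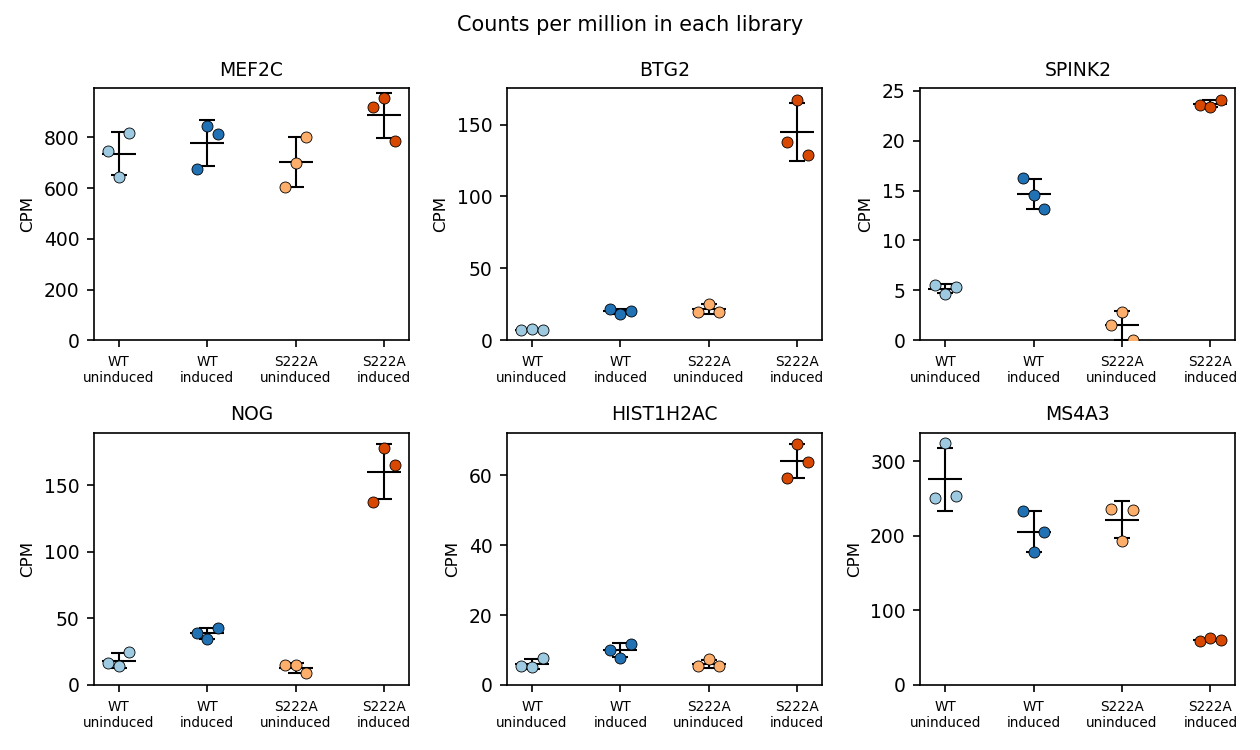
CPM of 6 genes (y axis, from 0) in the 4 groups (x axis), with a point per library, a dash for the mean and bars for the SD of n = 3. MEF2C means lie between 702.5 and 887.3 CPM, while SPINK2, NOG, HIST1H2AC and BTG2 are highest and MS4A3 is lowest in the S222A induced libraries.

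Doxycycline treatment of the WT line, with no called rise of MEF2C RNA, changed 1 gene. BTG2, an antiproliferative gene that p53 can activate, rose 2.77-fold from 7.32 ± 0.236 to 20.03 ± 1.9 CPM (SD, n = 3; log2 1.47 ± 0.20 SE, edgeR quasi-likelihood adjusted p = 0.0498). BTG2 did not overlap between the groups, but its call was lost without any 1 of the 6 WT libraries. Its adjusted p then ranged from 0.099 without WT induced replicate 2 to 0.483 without WT uninduced replicate 2. The call was also lost with upper quartile factors (0.0545), limma-voom (0.237) and without the deepest libraries (0.775). It was kept with DESeq2 (0.00191), and the log2 fold change of BTG2 stayed between 1.41 and 1.52 with single libraries left out. At an unadjusted p under 0.05 stood 195 genes, 139 higher and 56 lower. That is fewer than the share of 0.05 that chance gives over 11474 genes, so this count is not evidence of further changes. In 5.8% of genes the induced and uninduced libraries did not overlap, where chance gives 10%. A 4-fold change was recovered in 83.8% and a 2-fold change in 22.4% of simulated cases. Smaller changes were thus mostly not detectable with n = 3 and the depth and spread of these libraries.

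Among the gene lists, granulocyte granule and neutrophil markers fell on WT induction, with a median log2 fold change of -0.317 over 12 tested genes (camera adjusted p = 3.51e-05). This call held with an estimated correlation (adjusted p = 0.0291) and without each WT library in turn (up to 0.00508). No single gene of that list was called, nor any when adjusted over the list alone. PRTN3, the azurophil protease proteinase 3, stood at 10.95 ± 0.436 CPM uninduced and 5.11 ± 1.58 CPM induced (SD, n = 3). MYC targets and ribosome biogenesis genes fell as a list (median log2 -0.127 over 29 genes, 0 called over all genes and 0 adjusted over the list alone, adjusted p = 0.0117), a call that was lost at adjusted p = 0.0958 with an estimated correlation. Cell-cycle inhibitors rose as a list (median 0.082 over 12 genes, adjusted p = 0.0117; adjusted p = 0.0958 with an estimated correlation), with 1 member called over all genes and 1 adjusted over the list alone, BTG2. Mitochondrially encoded mRNAs rose as a list by a median of 0.192 over 13 genes, none of them called either way (adjusted p = 0.0352; adjusted p = 0.622 with an estimated correlation and 0.674 with fry). Fry also called proliferation genes, as lower (adjusted p = 0.0304; 0.0623 with camera). The calls of the MYC list, the inhibitors and the mitochondrial mRNAs were also lost without 4 or 5 of the 6 WT libraries. Their adjusted p reached 0.119 for the MYC list (without WT uninduced replicate 2), 0.116 for the inhibitors (without WT uninduced replicate 3) and 0.544 for the mitochondrial mRNAs (without WT uninduced replicate 1).

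Doxycycline treatment of the S222A line, with no rise of MEF2C RNA called in the main fit, changed 511 genes. Of these, 321 were higher and 190 lower, and 293 changed at least 2-fold. No treated cells without a MEF2C construct were analysed, so an effect of doxycycline itself is not separated. SPINK2, a serine protease inhibitor of haematopoietic progenitors, rose 13.5-fold to 23.7 ± 0.348 CPM (SD, n = 3; log2 3.75 ± 0.36 SE, edgeR quasi-likelihood adjusted p = 0.000133). The S222A uninduced libraries held 13, 7 and 0 counts of SPINK2, so this fold is uncertain. In the WT line SPINK2 stood at 4.64 to 5.55 CPM uninduced and 13.16 to 16.22 CPM induced, and was not called. NOG, the secreted BMP antagonist noggin, rose 11.8-fold from 12.9 ± 3.57 to 160.5 ± 20.5 CPM (log2 3.56 ± 0.24 SE, adjusted p = 5.99e-06). RGS1, a regulator of G-protein signalling, rose 11.3-fold to 104.6 ± 20.4 CPM (adjusted p = 0.000104). BTG2 rose 6.65-fold from 21.7 ± 3.28 to 144.7 ± 20.3 CPM (adjusted p = 5.99e-06). MS4A3, a marker of granulocyte-monocyte progenitors, fell 3.64-fold from 221.7 ± 24.6 to 60.9 ± 1.44 CPM (log2 -1.86 ± 0.17 SE, adjusted p = 8.26e-05). CDA, the cytidine deaminase that inactivates cytarabine, fell 3.77-fold from 14.0 ± 2.45 to 3.36 ± 1.14 CPM (log2 -1.91 ± 0.27 SE, adjusted p = 0.0015).

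Other large increases were in ABHD4, a lipid hydrolase (12.5-fold), HIST1H2AC, a core histone H2A gene (10.6-fold), and RASD1, a Ras-like GTPase (10.5-fold). They were followed by the chemokine receptor CXCR3 (9.83-fold), TRAC, the constant region of the T cell receptor alpha chain (8.73-fold), and SMIM14, a small membrane protein (8.49-fold). The other large decreases were in RXFP2, a relaxin family receptor (14.4-fold), HSD11B1, which regenerates cortisol (7.05-fold), CLEC4D, a C-type lectin of myeloid cells (5.70-fold), and CILP2 (4.19-fold). Smaller ones were in TFEC, a MiT family transcription factor (4.07-fold), TMEM45A (3.82-fold), NEO1, the receptor neogenin (3.74-fold), and CHST13, a chondroitin sulfotransferase (3.60-fold). The induced S222A libraries held 1, 2 and 7 counts of RXFP2 and 1, 1 and 10 of HSD11B1, so these folds are uncertain. The folds of ABHD4 and CXCR3 are uncertain as well, with 11, 2 and 0 counts of ABHD4 and 7, 7 and 4 of CXCR3 in the uninduced S222A libraries. TRAC and these 8 decreased genes lost their call when 1 library was left out. HSD11B1 lost it without S222A induced replicate 2 alone (adjusted p = 0.0528), TRAC without S222A uninduced replicate 1 or 2 (up to 0.0578), and the others up to 0.207 for CLEC4D without S222A uninduced replicate 2. The groups did not overlap in 27.5% of genes, where chance gives 10%. In all, 2193 genes stood at an unadjusted p under 0.05, 1130 higher and 1063 lower. With the term for the deepest libraries, chosen after seeing the data, 1006 genes were called higher and 1046 lower, so the larger share of higher genes was not kept. The count of called genes fell to between 187 (without S222A induced replicate 2) and 329 (without S222A uninduced replicate 3) when a library was left out. It was 233 and 203 without S222A uninduced replicates 1 and 2, and 216 and 208 without S222A induced replicates 1 and 3.

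Of the 33 lists tested, 17 were called on S222A induction, 9 higher and 8 lower, and 8 of these calls held with an estimated correlation. Fry, which asks whether a list moved at all and not whether it moved more than other genes, called 20 lists. MYC targets and ribosome biogenesis genes fell, with a median log2 of -0.615 (camera adjusted p = 3.19e-09; adjusted p = 0.00243 with an estimated correlation). In this list 0 of 29 tested genes were higher, 5 lower and 24 not called over all genes, and 17 were lower when adjusted over the list alone. Its lower members included the nucleolar factors NOP16 (log2 -0.84), DKC1 (-0.68) and NOLC1 (-0.67). Proliferation genes fell, with a median of -0.471, with 5 of 30 lower and 10 lower when adjusted over the list alone (adjusted p = 5.1e-08; 0.00243 with an estimated correlation). Among them were the replication helicase subunits MCM7 (log2 -0.56), MCM4 (-0.67) and MCM3 (-0.56). Heat shock and protein folding genes fell, with a median of -0.419 over 13 genes (2 lower, 7 adjusted over the list alone; adjusted p = 0.000771; 0.0214 with an estimated correlation), with the chaperones HSPH1 (log2 -0.78) and HSPD1 (-0.74). Each of these 8 named genes lost its own call when 1 library was left out, up to adjusted p = 0.18 for MCM3 without S222A induced replicate 1. The 3 list calls held without each S222A library in turn.

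Granulocyte granule and neutrophil markers fell further, with a median log2 of -1.075, with 6 of 12 tested genes lower both over all genes and adjusted over the list alone (camera adjusted p = 1.35e-07; adjusted p = 0.00354 with an estimated correlation). Beside MS4A3, the neutrophil protease CTSG fell 3.17-fold from 617.9 ± 99.4 to 195.1 ± 24.9 CPM (SD, n = 3; adjusted p = 0.00034). The calcium-binding protein gene S100P fell 2.07-fold (adjusted p = 0.00647), and PRTN3 fell 3.20-fold (adjusted p = 0.00771, lost at 0.0779 without S222A uninduced replicate 1). Monocyte and macrophage markers were not called as a list (median 0.292, adjusted p = 0.546, with 0 of 15 higher and 2 lower, 3 and 2 adjusted over the list alone). Its members S100A9 (log2 -1.47) and S100A8 (-1.32), alarmins of myeloid cells, fell. Both started above the WT line, with S100A9 at 120.36 to 209.16 CPM uninduced against 37.18 to 63.16 CPM in WT uninduced libraries. S100A8 stood at 24.09 to 39.04 against 9.46 to 17.57 CPM. In S222A induced libraries they stood at 41.85 to 71.35 and 11.43 to 12.28 CPM. S100A8 lost its call at adjusted p = 0.0953 without S222A uninduced replicate 1 and without each induced replicate (up to 0.0657). Myeloid transcription factors were not called either (adjusted p = 0.947), with RUNX2 higher (log2 1.26) and CEBPD lower (-1.004, lost at 0.0531 without S222A uninduced replicate 2 and at 0.054 without S222A induced replicate 3).

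HOXA/MEIS1 stem-cell programme genes rose by a median log2 of 0.663 on S222A induction, with 2 of 12 tested genes higher and 7 higher when adjusted over the list alone (camera adjusted p = 0.000112; adjusted p = 0.0148 with an estimated correlation). The homeobox genes MEIS1 (log2 0.78) and HOXA5 (0.87) were the 2 called. Their calls were lost without single libraries, up to adjusted p = 0.0734 for MEIS1 and 0.14 for HOXA5, both without S222A uninduced replicate 2. Cell-cycle inhibitors rose by a median of 0.491, with 3 of 12 higher and 6 adjusted over the list alone (adjusted p = 0.000771; 0.0214 with an estimated correlation), BTG2 and the CDK4/6 inhibitors CDKN2C (log2 0.70) and CDKN2D (0.93). CDKN2C and CDKN2D lost their calls without single libraries, up to 0.115 without S222A induced replicate 1 and 0.152 without S222A uninduced replicate 2. Type I interferon-stimulated genes rose by a median of 0.617, with 2 of 19 higher either way (adjusted p = 0.00122; 0.0214 with an estimated correlation), IRF7 (log2 1.57) and RSAD2 (2.94). These lost their calls up to 0.0922 and 0.0925 without S222A uninduced replicate 1. RSAD2 had 7, 2 and 0 counts in the S222A uninduced libraries, so its fold is uncertain. NF-kB and inflammatory cytokine genes rose by a median of 0.3, with 3 of 15 higher and 5 adjusted over the list alone (adjusted p = 0.00682; 0.0476 with an estimated correlation). TNFAIP3, an inhibitor of NF-kB signalling, rose 2.17-fold from 151.2 ± 35.7 to 325 ± 65.4 CPM (SD, n = 3; edgeR adjusted p = 0.00759). The apoptosis inhibitor BIRC3 rose 4.38-fold from 6.74 ± 1.66 to 30.1 ± 2.43 CPM (adjusted p = 0.00309).

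**Figure D3:**
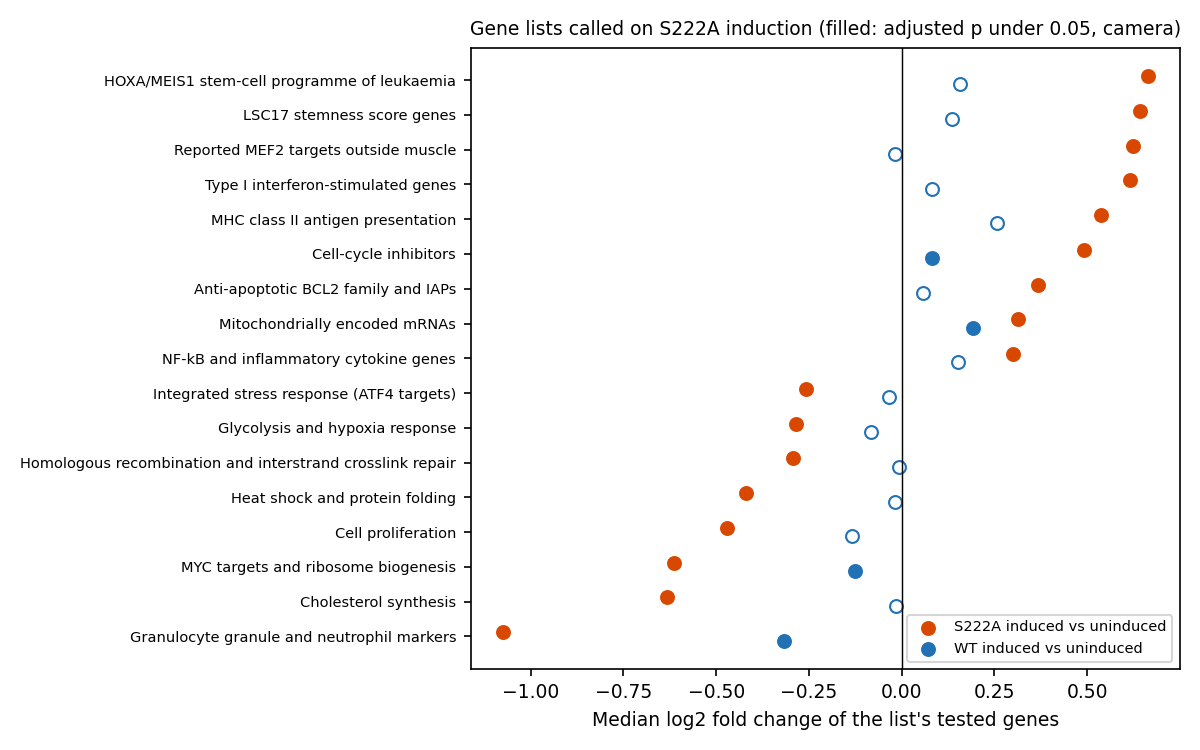
Median log2 fold change (x axis) of the tested genes of the 17 lists called on S222A induction (y axis), for S222A and WT induction, with filled points where the camera adjusted p was under 0.05. Medians range from -1.075 to 0.663 on S222A induction and from -0.317 to 0.258 on WT induction.

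The other 9 list calls on S222A induction were lost with an estimated correlation. Cholesterol synthesis genes fell, with a median log2 of -0.633 (1 of 18 higher and 2 lower, 1 and 9 adjusted over the list alone; camera adjusted p = 0.00044; adjusted p = 0.114 with an estimated correlation). In that list SQLE, squalene epoxidase, fell 2.23-fold from 91.3 ± 7.03 to 40.9 ± 5.49 CPM (SD, n = 3; edgeR adjusted p = 0.00117). INSIG1, which holds back the sterol-sensing activators of that pathway, rose 2.89-fold from 265.8 ± 31.7 to 771.1 ± 71.5 CPM (adjusted p = 0.00034). Homologous recombination and crosslink repair genes fell, with a median of -0.294, with none of 29 called either way (adjusted p = 0.000954; 0.136 with an estimated correlation). LSC17 stemness score genes rose by 0.642 (2 of 9 higher, 3 adjusted over the list alone; adjusted p = 0.00476; 0.114 with an estimated correlation), with C19orf77 (log2 2.19) and MMRN1 (0.97). Reported MEF2 targets outside muscle rose by 0.625 (2 of 11 higher, 3 adjusted over the list alone; adjusted p = 0.0206; 0.114 with an estimated correlation). Among them the MAP kinase phosphatase DUSP6 rose 2.87-fold from 114.2 ± 19.7 to 330.4 ± 44.7 CPM (adjusted p = 0.000741). That list call was lost at 0.0548 without S222A uninduced replicate 3. Anti-apoptotic BCL2 family and IAP genes rose by 0.367 (1 of 10 higher, BIRC3, and 2 adjusted over the list alone; adjusted p = 0.0233; 0.1 with an estimated correlation).

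The integrated stress response list fell, with a median of -0.257 (2 of 24 higher and 2 lower, 3 and 6 adjusted over the list alone; camera adjusted p = 0.0333; adjusted p = 0.318 with an estimated correlation). In it VLDLR (log2 1.34) and PPP1R15A (1.26) rose, and TRIB3 (-1.24) and PHGDH (-0.77) fell. PHGDH, which starts serine synthesis, lost its call up to 0.118 without S222A induced replicate 1. Glycolysis and hypoxia genes fell, with a median of -0.285 (1 of 20 lower, LDHA, 3 adjusted over the list alone; adjusted p = 0.0465; 0.318 with an estimated correlation). MHC class II genes rose by 0.537 (0 of 7 called, 1 adjusted over the list alone; adjusted p = 0.0465; 0.114 with an estimated correlation). Mitochondrially encoded mRNAs rose by 0.314 with none of 13 called either way (adjusted p = 0.0233; 0.389 with an estimated correlation), beside a mitochondrial share that also differed between the deepest and the other libraries. With fry the calls of the stress response (adjusted p = 0.23), glycolysis (0.244) and mitochondrial lists (0.101) were lost. All 4 list calls of this paragraph, MHC class II included, were lost without single libraries. Their adjusted p reached 0.14 and 0.189 for the stress response and glycolysis lists without S222A uninduced replicate 1, and 0.102 and 0.149 for MHC class II and mitochondrial mRNAs without S222A uninduced replicate 2. LDHA lost its call up to 0.149 without S222A uninduced replicate 2.

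The remaining 16 lists were not called on S222A induction, with camera adjusted p from 0.0521 for adhesion, homing and matrix invasion to 0.947 for myeloid transcription factors. Of these, fry called adhesion and drug transport (adjusted p = 0.000939 each), p53 targets (0.00746), pro-apoptotic genes (0.0115), TGF-beta, Notch and Wnt response genes (0.0243) and the unfolded protein response (0.0284). In the adhesion list 5 of 22 genes were higher and 2 lower (5 and 3 adjusted over the list alone). Higher were the matrix protease MMP14 (2.59-fold, from 299.2 ± 63.4 to 771.8 ± 33.8 CPM, SD, n = 3) and the integrin subunits ITGA6 (4.87-fold) and ITGB7 (2.75-fold). Drug transport and metabolism genes (median -0.339, adjusted p = 0.0754) included MVP, the major vault protein, higher by 4.13-fold, and CDA, lower (1 of 19 higher and 2 lower over all genes and adjusted over the list alone). Among the class IIa histone deacetylases and MEF2 partners (1 of 9 higher, 3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.3), HDAC9 was called (log2 0.91, lost up to 0.0729 without S222A uninduced replicate 1). HDAC4 (-0.55), HDAC5 (0.94) and HDAC7 (0.20) were not. MEF2-phosphorylating and related kinases were not called as a list (adjusted p = 0.371), with 1 of 12 higher either way, NUAK1 (log2 0.81, lost up to 0.111 without S222A induced replicate 1).

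In the other uncalled lists, the immediate-early phosphatase DUSP4 (6.26-fold higher), the pro-apoptotic BH3 gene BMF (2.28-fold), the TGF-beta receptor TGFBR2 (3.12-fold), HLA-E (1.73-fold) and HIST1H2BK (2.43-fold) rose. NLRC5, an activator of MHC class I genes, fell 2.05-fold (lost at 0.0617 without S222A induced replicate 2). The list adjusted p was 0.371 for immediate-early genes, 0.133 for pro-apoptotic genes, 0.247 for TGF-beta, Notch and Wnt response genes, 0.371 for MHC class I and 0.0757 for replication-dependent histones. It was 0.371 for p53 targets (1 of 25 higher, BTG2, and 2 adjusted over the list alone), 0.166 for cytosolic ribosomal proteins (0 of 40 called), 0.177 for nuclear-encoded respiratory chain subunits (0 of 33), 0.0754 for the unfolded protein response (0 of 16) and 0.0955 for nuclear-retained and small structural RNAs. In the last list MALAT1 rose 2.14-fold (lost up to 0.0948 without S222A uninduced replicate 2). Of the lists with too few tested members, none of 2 muscle MEF2 targets, 3 erythroid and 3 fibroblast, epithelial and endothelial markers was called. In others 1 of 3 was higher among megakaryocyte (RAB27B), B-lymphoid (VPREB1) and T and NK cell markers (TRAC). VPREB1, a surrogate light chain of pre-B cells, had 0 counts in the uninduced libraries of both lines. It had 99 counts on S222A induction (4.01 to 5.5 CPM per library) and 17 on WT induction (0 to 1.9 CPM, not called). VPREB1 and RAB27B lost their S222A calls without S222A uninduced replicate 1, at 0.0716 and 0.0912.

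The called sets of the inductions shared 1 gene, BTG2, which was higher in both, where independent sets of 1 and 321 higher genes would share 0.028. Of the 511 genes called on S222A induction, 437 (85.5%) had the same sign on WT induction, 87 of them at an unadjusted p under 0.05, and 0 genes had the opposite sign at that level. The 321 higher genes had a median log2 fold change of 1.29 on S222A and 0.26 on WT induction, and the 190 lower genes -0.86 and -0.18. These genes were chosen by their S222A call, which enlarges their S222A medians, so part of this gap is fixed by the choice. Over all genes tested the SD of the log2 fold changes was 0.554 on S222A and 0.318 on WT induction. The comparisons share no library. Across all 11474 genes, which are not independent replicates, the effects correlated with Pearson's r = 0.358 and Spearman's rho = 0.303.

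**Figure D4:**
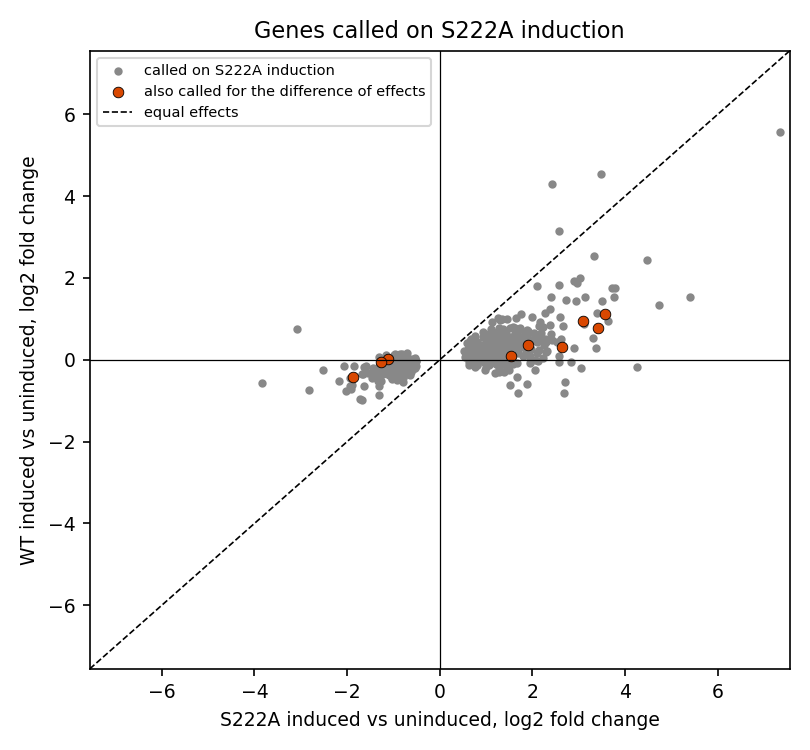
Log2 fold change on S222A induction (x axis) and on WT induction (y axis) of the 511 genes called on S222A induction, a point per gene, with the genes also called for the difference of effects in orange and a dashed line for equal effects. Most points lie nearer to 0 on the WT axis, which the choice of genes by their S222A call favours, and 85.5% of the genes have the same sign on both.

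The difference of the effects, which takes out what the uninduced lines already differed in, was called for 9 genes, 6 with a more positive effect in the S222A line and 3 with a more negative one. HIST1H2AC differed by 2.63 ± 0.34 (SE) on the log2 scale (edgeR adjusted p = 0.0184). Its levels were 6.11 ± 1.45, 9.93 ± 2.00, 6.05 ± 1.16 and 64.0 ± 4.84 CPM (SD, n = 3) in WT uninduced, WT induced, S222A uninduced and S222A induced libraries. NOG differed by 2.44 ± 0.32, from 18.4 ± 5.37 to 38.9 ± 4.08 CPM in the WT line, DUSP4 by 2.33 ± 0.32 and SMIM14 by 2.14 ± 0.30, all at the same adjusted p. RPS6KA5, a kinase downstream of MAP kinases, differed by 1.53 ± 0.24 (adjusted p = 0.0438) and INSIG1 by 1.44 ± 0.24 (0.0458). MS4A3 differed by -1.44 ± 0.23 (0.0438), MARC1, a mitochondrial reductase, by -1.22 ± 0.20 (0.0458) and BMP8B, a BMP family ligand, by -1.14 ± 0.18 (0.0438). Each call was lost without at least 8 of the 12 libraries. The adjusted p reached 0.0935 for HIST1H2AC and NOG without S222A induced replicate 2 and 0.248 for INSIG1 and MS4A3 without WT uninduced replicate 1, and the count of calls lay between 0 and 4. The fit without the deepest libraries, chosen after seeing the data, also called 9 genes but kept only NOG, SMIM14, INSIG1 and MS4A3 of these. It lost HIST1H2AC (adjusted p = 0.0727), MARC1 (0.0839), RPS6KA5 (0.096), BMP8B (0.122) and DUSP4 (0.212). In all, 766 genes stood at an unadjusted p under 0.05, where chance alone gives 0.05 of the 11474 genes, so many of them can be chance. In simulation 61% of 4-fold but 1% of 2-fold differences were recovered.

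The effects differed for 11 lists, and 6 of these calls held with an estimated correlation. The S222A effect was more negative for MYC targets and ribosome biogenesis (median difference -0.506, camera adjusted p = 1.34e-05; adjusted p = 0.01 with an estimated correlation), proliferation (-0.386, 2.63e-05; 0.01 estimated), granulocyte markers (-0.714, 0.000388; 0.0266 estimated) and heat shock genes (-0.454, 0.00462; 0.0454 estimated). It was more positive for HOXA/MEIS1 genes (0.57, 0.00364; 0.0454 estimated) and interferon-stimulated genes (0.535, 0.00462; 0.0454 estimated). The calls for cholesterol synthesis (-0.631, 0.000673), homologous recombination (-0.369, 0.00177), LSC17 genes (0.602, 0.00962), anti-apoptotic genes (0.311, 0.00962) and cell-cycle inhibitors (0.321, 0.0135) were lost, at adjusted p = 0.155, 0.169, 0.169, 0.0658 and 0.071 with an estimated correlation. Fry called 9 lists for the difference, without cholesterol synthesis (adjusted p = 0.0648), homologous recombination (0.101) and LSC17 genes (0.0644) and with adhesion (0.0272). Among members of these 11 lists, MS4A3 and INSIG1 were called over all genes. Adjusted over the list alone, 4 granulocyte genes and 1 cholesterol gene were lower, and 2 LSC17 genes, 1 anti-apoptotic gene, 1 cell-cycle inhibitor and 1 cholesterol gene were higher. The 11 list calls held without each of the 12 libraries in turn.

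Before induction the lines differed in 45 genes, 39 higher and 6 lower in S222A cells. CD82, a tetraspanin, was 4.42-fold higher at 46.4 ± 2.53 against 10.5 ± 0.926 CPM (SD, n = 3; log2 2.14 ± 0.16 SE, edgeR adjusted p = 6.42e-05). PLEKHO1 was 6.61-fold higher at 65.5 ± 14.4 against 9.54 ± 3.32 CPM (adjusted p = 0.000376). LIN7A, a cell polarity scaffold, stood at 17.0 ± 4.40 against 0.193 CPM, the latter from 3 counts in all (adjusted p = 0.000709). The entry for MIR146A, a microRNA gene induced by NF-kB, was 19.2-fold higher, with reads that can come from its longer host transcript (adjusted p = 0.000773). The WT uninduced libraries held 0, 7 and 3 counts of MIR146A, so this fold is uncertain. MSI2, an RNA-binding protein of haematopoietic stem cells, was 5.75-fold lower at 4.38 ± 2.42 against 26.8 ± 3.04 CPM (log2 -2.52 ± 0.32 SE, adjusted p = 0.00297).

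Other genes with large uninduced differences were higher for the amino acid oxidase IL4I1 (7.35-fold), the RNase ZC3H12A (7.07-fold), RAB13 (5.24-fold), PTAFR, the platelet-activating factor receptor (4.201-fold), FAM20C, a secretory kinase (4.12-fold), and CAMSAP2 (3.92-fold). They were lower for ZNF185 (4.13-fold), IFT57 (2.07-fold), METTL9 (1.91-fold) and BCAT1, which transaminates branched-chain amino acids (1.68-fold). Of these, ZC3H12A, RAB13, PTAFR, FAM20C, IFT57, METTL9 and BCAT1 lost their calls when 1 library was left out. Their largest adjusted p ran from 0.0507 for RAB13 without S222A uninduced replicate 1 to 0.232 for FAM20C without the same library. NF-kB and inflammatory cytokine genes were higher as a list (median log2 0.759, 4 of 15 higher, 6 adjusted over the list alone; camera adjusted p = 1.57e-07; adjusted p = 0.00805 with an estimated correlation), with TNFAIP3 at 2.88-fold (edgeR adjusted p = 0.00495). RELB, TNF and IL1B, the other 3 called, lost their calls up to 0.153 and 0.164 without WT uninduced replicate 1 and 0.218 without WT uninduced replicate 3. p53 targets were higher (median 0.278, 2 of 25 higher both over all genes and adjusted over the list alone; adjusted p = 6.47e-05; 0.0208 with an estimated correlation). These were BTG2 at 2.95-fold and the cell-cycle inhibitor CDKN1A at 2.85-fold (lost at 0.0511 without WT uninduced replicate 1). The groups did not overlap in 12.3% of genes, where chance gives 10%. At an unadjusted p under 0.05 stood 858 genes, 479 higher and 379 lower, so the split was less uneven than among called genes. Chance alone gives 0.05 of the 11474 genes, so many of these 858 can be chance. With the term for the deepest libraries 155 genes were called higher and 63 lower. Without a library the count of called genes lay between 17 (without WT uninduced replicate 1) and 30 (without WT uninduced replicate 2).

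Of the 33 lists, 8 further ones were called between the uninduced lines, and all 8 calls were lost with an estimated correlation. Cytosolic ribosomal proteins (median log2 -0.201, 0 of 40 called either way; camera adjusted p = 0.000173), MYC targets (-0.179, 0 of 29 either way; 0.00852), glycolysis (-0.196, 0 of 20 either way; 0.0191) and respiratory chain subunits (-0.129, 0 of 33 either way; 0.0226) were lower as lists. They stood at adjusted p = 0.306, 0.0642, 0.344 and 0.753 with an estimated correlation. With fry the ribosomal (0.107), glycolysis (0.237) and respiratory chain lists (0.498) were not called, and interferon-stimulated genes were, as higher (adjusted p = 0.0247; 0.0523 with camera). The unfolded protein response (0.257, 0 of 16 either way; 0.00852), adhesion (0.277, 1 of 22 higher, 2 adjusted over the list alone; 0.0119), cell-cycle inhibitors (0.218, 2 of 12 higher either way; 0.0158) and monocyte markers (0.497, 1 of 15 higher, 3 adjusted over the list alone; 0.0158) were higher. They stood at adjusted p = 0.0642, 0.0642, 0.0717 and 0.0717 with an estimated correlation. MMP14 in the adhesion list was 2.19-fold higher (lost at 0.0567 without WT uninduced replicate 3) and S100A9 among monocyte markers 3.09-fold higher (lost up to 0.138 without WT uninduced replicate 1). The cystine transporter SLC7A11, a member of the uncalled stress response list, was 3.36-fold higher. All of these 8 list calls but that of the ribosomal proteins were lost without 1 to 3 single libraries, up to 0.582 for the respiratory chain without WT uninduced replicate 2.

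After induction the lines differed in 727 genes, 428 higher and 299 lower in S222A cells, a comparison that holds the uninduced difference as well as the induction effects. MIR146A was 36.1-fold higher at 42.6 ± 3.8 against 0.799 ± 0.804 CPM (SD, n = 3; edgeR adjusted p = 1.71e-05). LIN7A was 20.4-fold (0.00053) and C3, the central complement component, 19.1-fold higher (0.0016), each against 5 counts in all in WT induced cells, so these folds are uncertain. IL4I1 was 17.2-fold (5.09e-05) and CXCR3 13.97-fold higher (0.00137). The WT induced libraries held 11, 0 and 3 counts of MIR146A and 14, 0 and 3 of CXCR3, so the folds of these 2 genes are uncertain as well. WDR35 was 8.03-fold (0.00622), AFAP1-AS1 7.64-fold (0.035), MSI2 7.195-fold (0.00017), IFT57 5.12-fold (1.21e-05) and ALDH1L2 4.94-fold lower (0.00886). AFAP1-AS1 lost its call up to 0.139 without S222A induced replicate 3. Among list members, MMP14 was 4.02-fold, BIRC3 9.33-fold, TNFAIP3 3.93-fold, RELB 3.92-fold and CDKN1A 2.29-fold higher. MYC, a driver of growth and ribosome production, stood at 90.35 ± 8.18 against 249.2 ± 52.7 CPM (log2 -1.47 ± 0.38 SE, adjusted p = 0.0389). Its call was lost without any 1 of the 6 induced libraries, up to 0.148 without S222A induced replicate 1. The groups did not overlap in 28% of genes, where chance gives 10%, and 2428 genes stood at an unadjusted p under 0.05. Without a library the count lay between 249 (without WT induced replicate 3) and 582 (without WT induced replicate 1). It was 445 without WT induced replicate 2, and 304, 277 and 343 without S222A induced replicates 1, 2 and 3.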

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

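Tests chosen after the result was seen are those of the MEF2C difference and of genes at an unadjusted p after thinning, and the term for the deepest libraries; the other tests weighed here were fixed before their values were computed.

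A test of the difference of the induction effects, S222A minus WT, marked 9 genes and 11 lists for a closer look. The genes were HIST1H2AC (log2 difference 2.63), NOG (2.44), DUSP4 (2.33), SMIM14 (2.14), RPS6KA5 (1.53), INSIG1 (1.44), BMP8B (-1.14), MARC1 (-1.22) and MS4A3 (-1.44). The lists, with the adjusted p of the difference, were HOXA/MEIS1 genes (0.00364), LSC17 genes (0.00962), anti-apoptotic genes (0.00962), homologous recombination (0.00177), granulocyte markers (0.000388) and proliferation (2.63e-05). The others were cell-cycle inhibitors (0.0135), MYC targets and ribosome biogenesis (1.34e-05), heat shock (0.00462), cholesterol synthesis (0.000673) and interferon-stimulated genes (0.00462). With an estimated correlation in camera, 5 of these 11 calls were lost. They were LSC17 genes (adjusted p = 0.169), anti-apoptotic genes (0.0658), homologous recombination (0.169), cell-cycle inhibitors (0.071) and cholesterol synthesis (0.155).

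Chance was not excluded for the number of these genes. In 12 of 100 assignments of the line labels within uninduced and within induced libraries, the real one included, at least as many genes as the real 9 were called, and the highest other count was 724. Of the 11 other assignments with as many, 10 kept the induced libraries of each line together, which leaves the difference between the induced lines in the contrast. The assignment with 724 genes kept both sets together, with the line labels swapped in 1 of them. Such assignments hold real line differences, so the share of 12 in 100 does not measure chance alone. Among the 82 that kept neither set together the highest count was 13. With the term for the deepest libraries, 10 of 100 assignments gave at least the real 147 genes, with 2383 as the highest other, and 9 of the 9 others kept the induced libraries together. For the lists, 14 of 100 gave at least the real 11, with 19 as the highest other, and 11 of the 13 others kept the induced libraries together.

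More genes were called on S222A than on WT induction, 511 against 1, which could reflect unequal depth, an aberrant WT library, more MEF2C RNA or the mutation. With every library thinned to the lowest total, 7 genes were called on S222A and 0 on WT induction in a first random thinning. In 5 further ones 15, 20, 10, 21 and 23 were called on S222A and 0 on WT induction. The criterion set before, above 10 times the WT count with 0 taken as 1, was thus met in 4 of the 6 thinnings, and this test leaves unequal depth open. At an unadjusted p under 0.05 the thinned S222A count was at least 6.7 times the WT count in each of the 5 further thinnings (737 to 781 against 84 to 114 genes). The WT counts lay below, and the S222A counts above, the share of 0.05 that chance gives over the 8970 to 9005 genes tested. The low WT counts enlarge this ratio, so its size is not a measure of effect. That the S222A excess remained at equal depth argues against depth as the whole cause. The highest WT count without 1 of the 6 WT libraries was 0, which met the criterion set before against 1 aberrant WT library. Fewer libraries also find fewer genes, as the S222A count then fell from 511 to between 187 and 329. This test therefore cannot exclude such a library. With the term for the deepest libraries 6 genes were called on WT induction. The difference of the MEF2C effects, 0.26 on the log2 scale (95% interval -0.27 to 0.8), left more MEF2C RNA open. Because each construct was carried by its own clones, the mutation could not be told apart from clone differences.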

How the results depend on the processing

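No called gene among the named ones, and no called list, turned direction in the alternatives run for it. Turns of genes that were not called were not counted. Among these, MEF2C on WT induction went from log2 0.08 to -0.01 without WT uninduced replicate 2. With every library thinned, 6 of the 511 genes called on S222A induction and 10 of the 727 called between the induced lines turned sign, and 76 and 94 were no longer tested. The WT count of 1 gene became 2 with DESeq2, 0 with upper quartile factors, 2 without the low-count filter, 0 with a minimum of 1 CPM, 0 with limma-voom (201 genes at an unadjusted p under 0.05), 0 with only the groups compared, 0 thinned (83 unadjusted), 6 with the term for the deepest libraries and 0 without those libraries (322 unadjusted), and 0 to 0 with 1 library left out. The overlap of 1 gene became 2, 0, 2, 0, 0, 0 (thinned), 6 and 0 in the same order, save only the groups compared, and 0 to 0 with 1 library left out. The S222A count of 511 became 7 thinned (10 to 23 in 5 further random thinnings; the other thinned counts are from the first alone), 2052 with the term, 293 with the fold minimum and 187 to 329 with 1 library left out, and was 727 with DESeq2, 704 with limma-voom and 553 without the deepest libraries. The difference count of 9 became 35 with DESeq2, 22 without the filter, 4 with the CPM minimum, 0 thinned (267 unadjusted), 147 with the term and 0 to 4 with 1 library left out, and was 9 without the deepest libraries, 4 of them the same genes. Between the induced lines 727 became 482 with only the groups compared, 20 thinned, 2480 with the term, 365 with the fold minimum and 249 to 582 with 1 library left out. Between the uninduced lines 45 became 72 with DESeq2, 91 without the filter, 9 with only the groups compared, 0 thinned (275 unadjusted), 218 with the term and 17 to 30 with 1 library left out. MEF2C on S222A induction kept its log2 of 0.34 with the term, at an adjusted p = 0.0282, and ranged from 0.25 to 0.44 with 1 library left out, from -0.01 to 0.17 on WT induction and from 0.09 to 0.26 between the induced lines. With an estimated correlation the called lists numbered 1 of 4 on WT induction, 8 of 17 on S222A induction, 6 of 11 for the difference and 2 of 10 between the uninduced lines, where 5 were called without the deepest libraries. With fry they numbered 4, 20, 9 and 8. With 1 library left out the camera calls numbered 2 to 3, 15 to 21, 11 to 15 and 4 to 12. A term for the replicate number, which does not pair these samples, gave 0 WT genes (153 unadjusted), an overlap of 0, 235 S222A genes, 0 difference genes (569 unadjusted), 350 between the induced and 22 between the uninduced lines, with residual degrees of freedom spent on it. Thinning, leaving out libraries and fitting fewer groups use fewer counts or samples by construction, the fold minimum asks for larger changes, and the term takes out a spread between libraries, with a biological coefficient of variation of 12.9% against 24.8%. For the other alternatives the cause was not tested. Depth limits what can be found, since the smallest library held 875710 counts. The term and the fit without the deepest libraries were chosen after seeing the data.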

Other observations

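Tests chosen after the result was seen are those of the S222A line before induction and of the share of genes moving the same way; the tests of the deepest libraries and of other groupings were fixed before their values were computed.

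Among the 39 genes higher in S222A than in WT cells before induction, 10 also rose on doxycycline treatment of the S222A line. These included CAPG, an actin-capping protein (log2 1.3 before induction and 1.73 on induction), CYP1B1, a cytochrome P450 (1.35 and 1.38), and ZFP36L1, which promotes decay of AU-rich mRNAs (1.44 and 2.1). Another 6 of the 39 fell on induction, among them LPL, lipoprotein lipase (0.98 and -1.33), and SRGN, the granule proteoglycan serglycin (0.87 and -1.02). Of the 6 lower genes 2 also fell, IFT57 (-1.05 and -1.6) and BCAT1 (-0.74 and -0.72), and 0 rose. These comparisons share the S222A uninduced libraries with opposite signs, so no chance value is set beside the counts. Genes outside the naming rule, CAPG, CYP1B1, ZFP36L1, LPL and SRGN, were chosen after their values were seen.

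Leaky expression of the construct could make the S222A line resemble its induced state before induction. The comparisons share the S222A uninduced libraries with opposite signs, so their covariance across genes, which are not independent, was set against 20 simulations of unchanged groups. It was -0.0115, against -0.0814 on average in the simulations (-0.0863 to -0.0749), and against -0.0383 (-0.0404 to -0.0354) with the smaller spread of the fit with a term for the deepest libraries. The real value lay above all simulated ones but not above 0, and the criterion asked for both. The shared libraries pull the covariance below 0, so a value under 0 is no sign against a resemblance. The simulated values also moved with the spread assumed, so this test cannot decide and the resemblance stays open. MEF2C was not called between the uninduced lines (fold 0.95, 95% interval 0.73 to 1.24). Both lines carried a MEF2C construct and transgene reads are not separated, so this neither shows nor excludes leaky expression.

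The deepest library of each group stood apart on component 1, and a term for these libraries called 4410 genes, 2209 higher and 2201 lower. Depth alone may contribute, since 1 random thinning of every library to the lowest total narrowed the gap from 37.3% to 11.2% of the range of component 1 without closing it, which leaves depth open. The fold between the sets correlated with GC content at Spearman's rho = 0.324 over 10290 genes, which are not independent, a size that fits a GC bias by the criterion set before. With transcript length rho was -0.201, which leaves a length bias open. Each group holds 1 such library, and no biological explanation was tested.

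For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05, so chance was neither excluded nor shown. The real S222A split gave 511 genes and the highest other 0 (1 of 10 gave as many, the real one itself), the induced lines 727 and 0 (1 of 10), and the uninduced lines 45 and 0 (1 of 10). For WT induction 2 of 10 splits gave at least the real 1 gene, and the highest other, 109, is many times the real count and points to a structure of the samples. That split put both deepest WT libraries on the same side, but the 3 other splits that did so called 0 genes, so what the structure is stays open. Lists gave 4 against 6 as the highest other on WT induction (3 of 10), 17 against 9 on S222A induction (1 of 10) and 10 against 5 between the uninduced lines (1 of 10). The share of S222A-called genes moving the same way on WT induction was 85.5%, against 73% as the highest other (1 of 10). For the overlap of calls, 2 of 100 joint splits reached the real 1 gene, with 14 as the highest other, but no S222A split other than the real one called a gene. The overlap was therefore fixed at 0 in 90 of the 100, and the splits do not show whether chance can be excluded.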
